A study of Caenorhabditis elegans with 6 samples.

How the data were processed

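RNA from whole Caenorhabditis elegans larvae arrested in the first larval stage (L1 arrest) was sequenced in 6 libraries, 3 from the N2 wild type and 3 from a strain carrying the allele aqz 3 of linc-133, a long intervening noncoding RNA gene. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the libraries were made with a TruSeq RNA kit, which does not mark the strand of a read, and were read on an Illumina GAIIx. The submitters' processing notes name Bowtie 0.12.2, STAR 2.5.2b, StringTie and the genome build WBcel235, without saying which step each was used for. The strand setting of the counting and the annotation release are not given in the sources used here. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

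The values deposited by the authors are FPKM (fragments per kilobase of gene length, scaled to the reads of the library), per the file headers, for 45519 genes, with the gene length, position and type beside each gene. Multiplying each FPKM by its gene length gave whole multiples of 1 step per library: 100% of 131954 values above 0 lay within 0.01 of a whole read, with a largest distance of 2.83e-05. The reads behind each value could therefore be recovered. The read total implied by that step was between 0.9004 and 1.117 times the recovered total of the library, so a scaling between libraries was already part of the authors' values. Median-of-ratios factors computed from the FPKM were 1.008 in each of the 6 libraries, so that rescaling by them changed next to nothing. A comparison of the table with the WBcel235 annotation matched 42591 gene symbols, of which 99.87% overlapped on the same chromosome and 83.25% had identical ends. The 13 tested genes of the mitochondrial chromosome carry a dash in place of a gene type and were kept in the tests.

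Genes with a mean of at least 1 FPKM over the 6 libraries were tested (16794 genes). The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend in the prior variance, robust moderation, the group as the only term and all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was the threshold. As the table holds FPKM, no count model was used for the main test. Of the tested genes, 2631 had a mean of fewer than 10 recovered reads, among them 1565 piRNA genes of 21 bases in which a single read is worth 2.31 to 3.05 FPKM. After these had been seen, further tests were added: a filter at a mean of 10 recovered reads, limma's voom on the recovered reads, voom with a quality weight per library, values without the authors' scaling, and protein-coding genes alone.

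Before the data were examined, 44 gene lists were fixed: pathways of starvation and stress, cell type markers, and markers of other stages that a harvest of larvae could carry over. Lists with at least 5 tested genes (43 of 44) were tested with limma's camera at a preset correlation of 0.01 between genes, and also with an estimated correlation and with fry. Members were counted after adjustment over all genes and after adjustment over the list alone. Genes within 50 kb of linc-133 were also adjusted among themselves. linc-133 itself was compared with a 2-sided exact permutation test, for which 0.1 is the smallest p that 3 libraries against 3 allow. The interval of its read ratio is an exact binomial 95% interval and covers counting error only. The share of called genes per chromosome and per gene type had been planned as a Fisher exact test, which was not run since no gene passed the main test.

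The genes named were chosen by a rule fixed before the data were examined: linc-133; the 12 higher and 12 lower genes of largest change among those past the threshold, which named no gene here; up to 4 members with the lowest p of each list past the set test; the highest-expressed member of each other-stage list; and the genes next to linc-133. Every other gene named was chosen after its values were seen, which is repeated where it matters.

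The gene test and the list test were tested on simulated libraries for this comparison. These held the 14163 genes with a mean of at least 10 recovered reads, not all 16794 tested genes. Each gene had the within-strain spread of the real data, with counting noise drawn on top of it. The rates below are therefore not exactly those of the main test. Of 118 genes changed 2-fold, 37.3% were called, and of 82 genes changed 4-fold, 75.6%, with the right sign in 100% of the calls. Among the unchanged genes 11 were called and 4.91% had a p under 0.05. A raised list was called and 0 of 50 random lists were. With 0.5 times that spread, 78.9% of 109 genes changed 2-fold and 96.7% of 91 genes changed 4-fold were called. Noise was drawn for each gene apart, so the simulated genes were not correlated with each other. The simulation therefore cannot show how often camera at the preset correlation calls a list of correlated genes.

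Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, median-of-ratios and quantile scaling, limma with neither trend nor robust moderation, the replicate number as a block, each library left out in turn, adjusted p thresholds of 0.01 and 0.1, a 2-fold minimum, and, for the lists, the other set tests and lists without shared members. Figures were drawn with matplotlib 3.10.9.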

Results

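Gene expression was measured by RNA sequencing in whole C. elegans larvae that had hatched without food and stopped at the first larval stage, after 3 days in M9 buffer at 20 °C. There were 6 libraries, 3 of the N2 wild type and 3 of the linc-133(aqz 3) mutant. The recovered reads on genes came to 18556695, 18104344 and 16758445 in wild-type replicates 1, 2 and 3, and to 18440824, 16108063 and 17322012 in mutant replicates 1, 2 and 3. Of 45519 listed genes, 27311 had a read in at least 1 library and 16794 reached the mean of 1 FPKM needed for testing.

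The first comparison asked whether the targeted transcript differed between the strains. linc-133 (gene 24104872, lncRNA) lies on chromosome II from 7837826 to 7841485 on the plus strand of WBcel235, with 2 exons. It was close to the detection limit in both strains, at 0.110 ± 0.0283 FPKM in wild type and 0.0546 ± 0.0288 FPKM in the mutant (SD, n = 3 each; exact permutation p = 0.1, the smallest that this design allows). The reads behind these means were 9, 6 and 5 in the wild-type libraries and 6, 2 and 2 in the mutant libraries. The mutant to wild-type ratio of reads was 0.517, with a 95% counting interval of 0.216 to 1.16, so a difference was not detectable at this depth. linc-133 overlaps linc-110, which runs on the minus strand from 7836075 to 7841128, and 865 of its 3317 exonic bases are shared with that gene. Reads in the shared part cannot be told apart by strand. The labels do not say which part of linc-133 the allele affects, so remaining reads do not test the genotype.

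**Figure D1:**
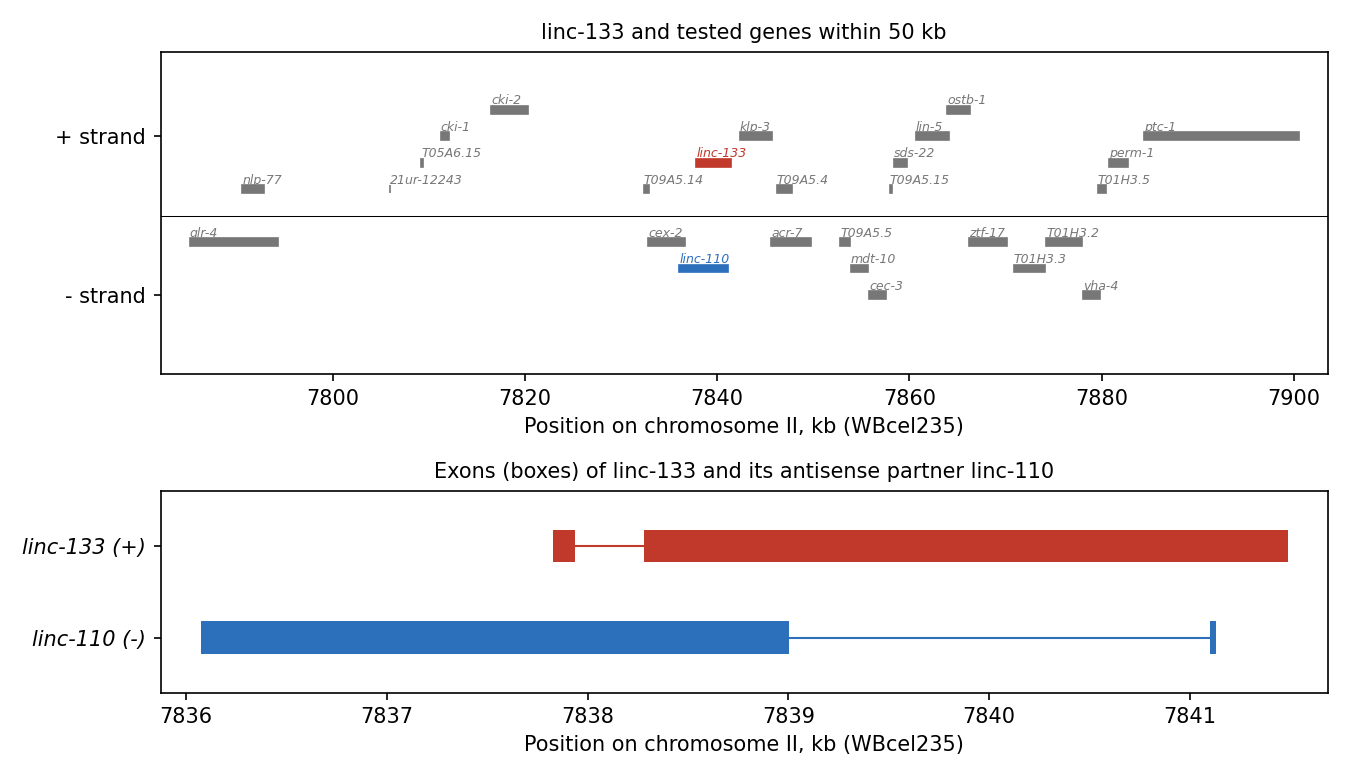
Map of chromosome II (position in kb, WBcel235) with linc-133 in red, linc-110 in blue and the other tested genes within 50 kb in grey, plus strand above the line and minus strand below. The lower panel shows the exons of linc-133 and linc-110 as boxes, which share 865 exonic bases.

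The genes around linc-133 were compared next, to see whether expression at the locus differed with the allele. Of 57 genes within 50 kb, 26 were tested, and 0 passed limma's test either over all genes or when adjusted over these neighbours alone (lowest adjusted p = 0.1998). Unadjusted p-values under 0.05 in limma were found for 4 of these 26. Over all tested genes it was 2301 of 16794, a similar share, so the neighbours did not stand out. The calexcitin gene cex-2 lies upstream of linc-133 on the minus strand, from 7832838 to 7836615, so that its start faces linc-133. cex-2 measured 30.2 ± 6.54 FPKM in wild type and 45.6 ± 7.69 FPKM in the mutant (SD, n = 3 each). The next gene in that direction with such a p, nlp-77, measured 508 ± 98.9 FPKM in wild type and 718 ± 60.01 FPKM in the mutant. On the other side, the Mediator subunit gene mdt-10 measured 11.96 ± 1.07 and 15.4 ± 1.40 FPKM, and T01H3.2 measured 10.7 ± 0.268 and 7.39 ± 0.519 FPKM, in wild type and mutant in that order. The cyclin-dependent kinase inhibitor genes cki-1 and cki-2, which restrain cell division, lie within the same window. cki-1 measured 57.6 ± 9.45 FPKM in wild type and 66.7 ± 3.47 FPKM in the mutant, and cki-2 measured 16.404 ± 1.11 and 17.5 ± 1.90 FPKM, with overlapping libraries in both genes. The antisense gene linc-110 had 46, 54 and 62 reads in the wild-type libraries and 34, 69 and 150 in the mutant libraries. The spans of linc-110 and cex-2 overlap on the same strand, from 7836075 to 7836615, so reads there may belong to either gene.

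Expression over all genes was then compared between the mutant and the wild type. The gene with the lowest p among those with more than a few reads was anmt-3 (gene 179385, chromosome V, 9956879 to 9958331), which encodes an amine N-methyltransferase. It measured 36.1 ± 6.48 FPKM in wild type and 163 ± 28.3 FPKM in the mutant, a 4.53-fold difference of means (SD, n = 3 each). Y22D7AL.10, annotated as the mitochondrial 10 kDa heat shock protein, measured 75.04 ± 3.47 FPKM in wild type and 177 ± 11.5 FPKM in the mutant. Their adjusted p-values of 0.0649 in limma missed the threshold. In the same way the acyl-CoA-binding protein gene acbp-6 was 2.95-fold higher in the mutant, the LIN-8 domain gene lido-15 2.37-fold, the glucuronosyltransferase gene ugt-11 2.405-fold and the Hsp90 co-chaperone gene daf-41 1.87-fold. On the lower side, the linker histone gene hil-1 measured 500.01 ± 40.2 FPKM in wild type and 246 ± 23.9 FPKM in the mutant. madf-9 was 2.57-fold lower in the mutant, the sulfotransferase gene ssu-1 2.72-fold and scb-1 1.95-fold. In each of these genes the 3 mutant libraries lay outside the range of the 3 wild-type libraries, and each was picked after its values were seen.

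In limma's test 0 of 16794 genes passed an adjusted p of 0.05. An unadjusted p under 0.05 was found for 2301 genes, 1213 higher and 1088 lower in the mutant, where 839.7 would be expected with no difference. The libraries of the strains did not overlap in 20.05% of the genes, against 10% by chance. At an adjusted p of 0.1 there were 9 genes, 2 higher (anmt-3 and Y22D7AL.10) and 7 lower (ZK792.12 and 6 piRNA genes that were listed at 0 in every mutant library and rested on few reads). At that threshold 167 genes passed with a filter at 10 reads (115 higher, 52 lower) and 172 with voom on the recovered reads (39 of them lower). The count depended on the test: anmt-3 alone passed with a filter at 10 reads (adjusted p = 0.0439) and with voom on the recovered reads (adjusted p = 0.0200), 23 genes (6 higher, 17 lower) passed in limma with neither trend nor robust moderation, and 288 (233 higher, 55 lower) passed in voom with a quality weight per library.

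The gene lists were compared to see which known groups of genes differed between the arrested larvae of the strains. The list of cytosolic chaperones and small heat shock proteins, which keep other proteins folded, was higher in the mutant in camera with its preset correlation (adjusted p = 2.25e-16 over 43 lists). The call was lost when the correlation between its members was estimated, at 0.36 (p = 0.0453, adjusted p = 0.976 with an estimated correlation), and fry's directional test did not pass (adjusted p = 0.306). Estimating raised p even without a higher correlation. The list of translation initiation and elongation had an estimated correlation of 0.00425, below the preset 0.01. Its unadjusted camera p was 0.0681 at the preset and 0.117 with the estimate. The loss of a call is therefore not due to the correlation alone, and no list passed with an estimate. Of 31 chaperone list members tested, 20 were higher and 0 lower when adjusted over the list alone, 11 did not pass, and 0 passed over all genes. The median change was 0.97 on the log2 scale, and in 24 members every mutant library lay above every wild-type library. The Hsp70-Hsp90 organising co-chaperone gene sti-1 (chromosome V, 773518 to 782264) measured 66.3 ± 5.80 FPKM in wild type and 234.7 ± 71.3 FPKM in the mutant (SD, n = 3 each), a 3.54-fold difference of means. The small heat shock protein gene hsp-17 (chromosome V, 8384799 to 8385933) measured 59.8 ± 11.2 and 205 ± 57.1 FPKM. hsp-16.11 measured 27.7 ± 12.1 FPKM in wild type and 170.5 ± 73.8 FPKM in the mutant, and hsp-16.49 measured 18.3 ± 9.32 and 124 ± 57.5 FPKM. These 2 genes have near-identical copies in the genome, so their own levels are uncertain. The constitutive Hsp70 gene hsp-1 measured 763 ± 61.3 FPKM in wild type and 2227 ± 1272 FPKM in the mutant.

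The members that did not pass included the small heat shock protein genes hsp-12.3 and hsp-12.6, which had lower means in the mutant, at 183.2 ± 50.6 FPKM against 227 ± 41.3 FPKM for hsp-12.3 and 194 ± 16.97 FPKM against 229 ± 47.5 FPKM for hsp-12.6. Libraries also differed within a strain. hsp-16.2 measured 473, 102 and 105 FPKM in wild-type replicates 1, 2 and 3, and 1101, 1767 and 3573 FPKM in mutant replicates 1, 2 and 3. The heat-inducible Hsp70 gene hsp-70 was likewise 3.42 times as high in wild-type replicate 1 as in the mean of the other wild-type libraries.

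**Figure D2:**
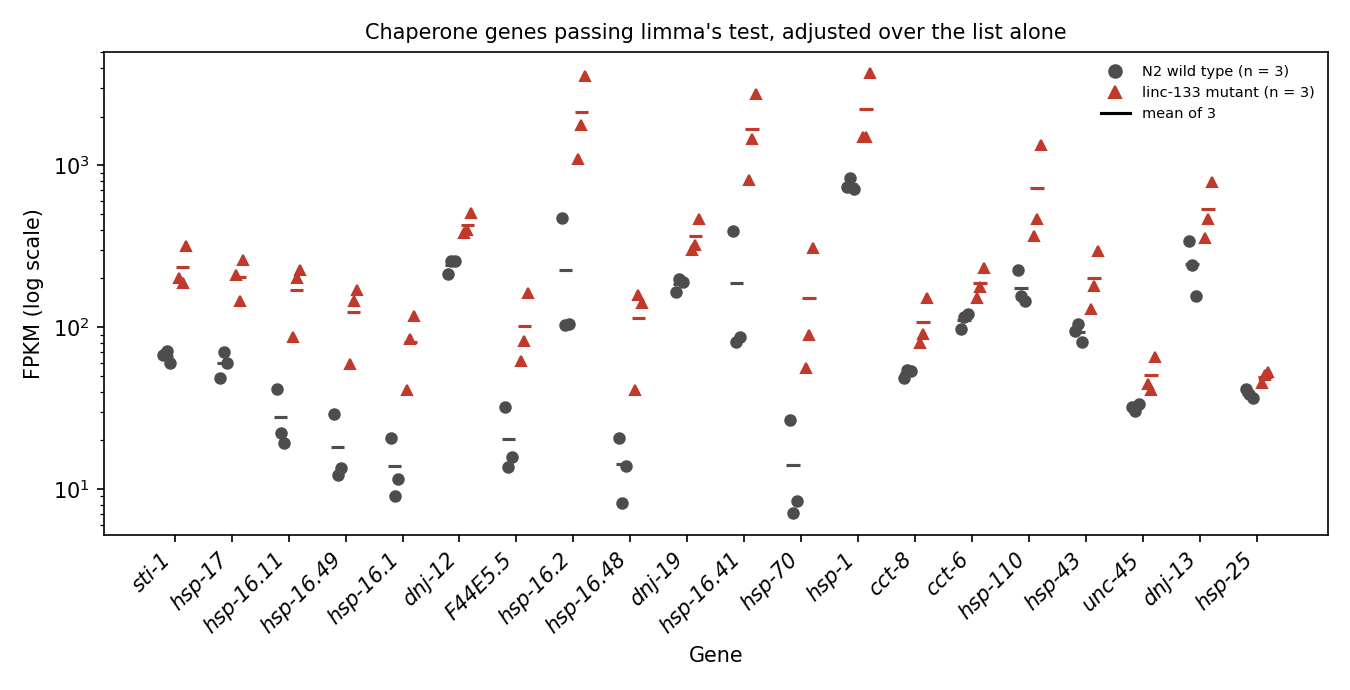
FPKM on a log axis for the 20 chaperone genes that passed limma's test adjusted over the list alone, in order of p, with 1 point per library (3 wild type as grey circles, 3 mutant as red triangles) and a bar at each mean of 3. Every mutant point lies above every wild-type point in each gene, with averages of 2147 against 227 FPKM for hsp-16.2 and 49.5 against 38.8 FPKM for hsp-25.

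The intracellular pathogen response is a group of genes induced by microsporidia and viruses in worms. Its list held 30 tested pals genes and 10 others, and whether each is induced by infection was not checked. As a list they were lower in the mutant in camera at the preset correlation (adjusted p = 4.05e-07). The call was lost with an estimated correlation (adjusted p = 0.976 with an estimated correlation). Of 40 members tested, 37 had a negative log2 change, with a median of -0.54, and 14 had an unadjusted p under 0.05, all of them lower. None passed over all genes, and 0 passed adjusted over the list alone. Many members are weakly expressed, and with a pseudocount of 5 the median was -0.27. By library, the median member measured 5.41, 8.44 and 8.71 FPKM in wild-type replicates 1, 2 and 3 and 5.64, 3.89 and 5.63 FPKM in mutant replicates 1, 2 and 3, so that wild-type replicate 1 lay at the level of mutant replicates 1 and 3. pals-31 (chromosome V, 636581 to 637518) measured 13.6 ± 1.65 FPKM in wild type and 6.63 ± 1.47 FPKM in the mutant (SD, n = 3 each). The Skp1-related ubiquitin ligase gene skr-5 measured 18.7 ± 4.76 and 8.39 ± 2.02 FPKM, pals-11 measured 3.10 ± 0.916 and 0.819 ± 0.331 FPKM, and pals-5 measured 3.29 ± 0.289 and 1.18 ± 0.705 FPKM. The 3 members with a positive log2 change were pals-16, pals-17 and drh-1.

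The early embryo list, meant to show embryos left among the larvae, was higher in the mutant in camera with its preset correlation (adjusted p = 0.000299), with a median change of 0.28 over 48 tested members. The call was lost with an estimated correlation (adjusted p = 0.976 with an estimated correlation) and among genes with a mean of at least 5 FPKM (median 0.13, adjusted p = 0.112). The median was 0.16 without wild-type replicate 2, 0.42 without wild-type replicate 1, and 0.16 with a pseudocount of 5. Only vet-1 and vet-6, named as very early embryonic transcripts, passed when adjusted over the list alone, and 0 members passed over all genes. vet-1 (chromosome I, 6200794 to 6202076) measured 6.32 ± 0.631 FPKM in wild type and 16.8 ± 3.52 FPKM in the mutant, and vet-6 measured 3.27 ± 0.471 and 6.79 ± 0.569 FPKM (SD, n = 3 each). Among transcripts named for their dependence on the embryonic regulator SKN-1, sdz-30 measured 3.39 ± 0.578 and 10.9 ± 4.24 FPKM and sdz-26 measured 1.95 ± 0.643 and 3.95 ± 0.262 FPKM. The most abundant member, sdz-24, measured 234 ± 80.2 FPKM in wild type and 292 ± 136 FPKM in the mutant, within the spread of the libraries. Of members that mothers load into the egg, pos-1 measured 112 ± 37.3 and 127 ± 22.1 FPKM, and mex-5 measured 42.1 ± 12.4 and 40.9 ± 2.54 FPKM, both with overlapping libraries.

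**Figure D3:**
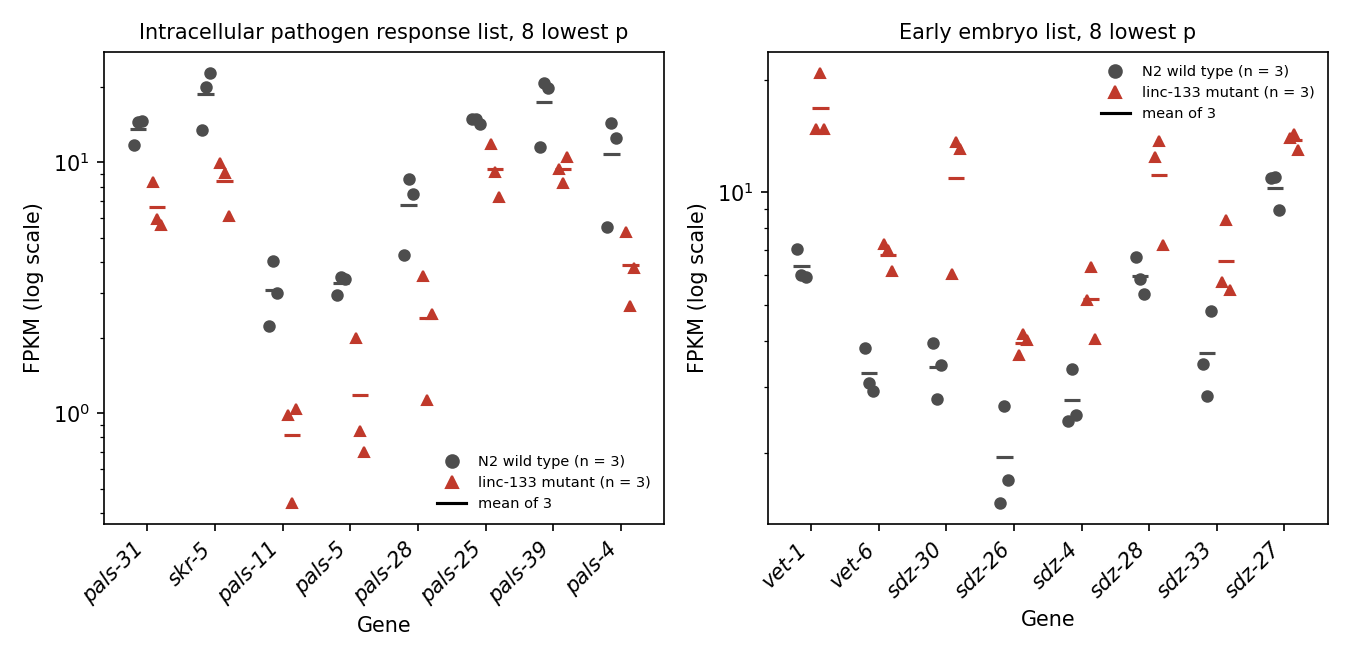
FPKM on log axes for the 8 members with the lowest p of the intracellular pathogen response list (left) and of the early embryo list (right), with 1 point per library (3 wild type as grey circles, 3 mutant as red triangles) and a bar at each mean of 3. pals-31 averages 13.6 FPKM in wild type and 6.63 FPKM in the mutant, and vet-1 averages 6.32 and 16.8 FPKM.

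The other 40 lists tested did not pass camera (lowest adjusted p = 0.151), and in 9 lists the median and the mean differed in sign, with medians within 0.0490 of 0. Among them, insulin-like peptides, insulin signalling, the starvation and fasting response, ribosomal proteins and markers of neurons, body wall muscle, pharynx, intestine, epidermis and glia had adjusted p-values of 0.862, 0.47, 0.681, 0.665, 0.862, 0.862, 0.862, 0.671, 0.862 and 0.862 in that order. In the list of targets of DAF-16, the transcription factor that insulin signalling holds back, 7 members were higher and 3 lower when adjusted over the list alone, out of 22, and the list itself had an adjusted p of 0.47. The higher members were hsp-16 genes already in the chaperone list, the desaturase gene fat-5 and the isocitrate lyase gene icl-1, which measured 239 ± 97.2 FPKM in wild type and 711 ± 323 FPKM in the mutant. The lower members were hil-1, the ferritin gene ftn-1 and the metallothionein gene mtl-1. Of the mitochondrial stress list only hsp-60 passed when adjusted over the list alone, with 14.7 ± 1.52 FPKM in wild type and 37.2 ± 14.9 FPKM in the mutant.

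Markers of other stages were checked for carry-over. The vitellogenins, yolk proteins made by adults, stayed under 1 FPKM, the highest over both strains being vit-3 with 0.412 ± 0.0801 FPKM in wild type and 0.35 ± 0.154 FPKM in the mutant. The highest member of the sperm list, spe-48, measured 33.9 ± 2.08 and 23.5 ± 2.67 FPKM. For the germline list it was cey-2, with 75.5 ± 24.1 and 95.5 ± 18.8 FPKM, for the late embryo list cpz-1, with 281 ± 11.2 and 326 ± 15.3 FPKM, and for the list of later growth lin-28, with 162 ± 10.1 and 144 ± 23.6 FPKM. Adjusted p-values of these lists in camera were 0.665, 0.506, 0.193 and 0.151. Whether such members are also expressed in the arrested larvae themselves was not tested, so their levels alone do not show carry-over.

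The number of lists past camera's threshold moved with single libraries: it was 8 without wild-type replicate 1, 8 without mutant replicate 1, 6 without mutant replicate 2 and 7 without mutant replicate 3, against 3 with all 6. Each of the 9 other ways to split the 6 libraries into groups of 3 gave more lists past the threshold, 8 to 19, so a camera call at the preset correlation does not set a list apart here. The libraries were similar as a whole. Pearson's r across genes of log2(FPKM + 1) was 0.933 to 0.944 between wild-type libraries, 0.9044 to 0.9354 between mutant libraries and 0.904 to 0.9377 between strains. The first principal component held 30.4% of the variance, with wild-type libraries at -18.3, -34.1 and -36.7 and mutant libraries at -9.79, 37.1 and 61.8. The second held 24% and did not separate the strains, with wild-type libraries at 9.95, -23 and -27.4 and mutant libraries at 44.7, 36.8 and -41.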

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

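The tests with recovered reads, with voom, without the authors' scaling and on protein-coding genes alone were added after the data were seen. The count of 0 genes was the same with either pseudocount, with each filter on FPKM, after quantile scaling, without the authors' scaling, at an adjusted p of 0.01 and without any 1 of the 6 libraries (0 to 0). Median-of-ratios scaling moved next to nothing and is no test of the scaling. The count was 23 in limma with neither trend nor robust moderation, 9 at an adjusted p of 0.1, 1 with the filter at 10 recovered reads, 1 with voom, 1 among protein-coding genes and 288 in voom with quality weights, which gave the least weight to mutant replicate 3 (0.404) and mutant replicate 1 (0.55). The voom count was 64 without wild-type replicate 1, 172 without mutant replicate 1 and 0 without each of the others. The number of lists past the threshold was 3 to 8 without 1 library, 0 with camera's estimated correlation, 0 with fry's directional test and 18 with its mixed test. Under the estimated correlation the list medians of 0.97, -0.54 and 0.28 stayed as they were, by construction, and their calls were lost. The early embryo median was 0.13 at a mean of at least 5 FPKM, past no threshold, with fewer genes tested. The chaperone count adjusted over the list alone was 15 to 24 without 1 library. The neighbours passing stayed at 0 under each alternative run, the 20 kb window included. The difference of linc-133 means was -0.07 to -0.04 FPKM without 1 library. Among single genes, sdz-24 (log2 change 0.25) was reversed to -0.063 without mutant replicate 2 and was at most 0.69, without mutant replicate 1, and the cause was not tested. anmt-3 passed in limma with neither trend nor robust moderation, with the filter at 10 reads, with voom and among protein-coding genes. In the 748 other recomputations of single genes at an adjusted p of 0.05, the direction and the side of the threshold were the same. With pseudocounts of 0.1 and 5 the median of the intracellular pathogen response was -0.66 and -0.27, that of the early embryo list 0.41 and 0.16, and that of the chaperones 0.98 and 0.94, each past camera's threshold at the preset correlation. With the replicate number as a block, 0 genes passed. The same-numbered libraries had correlations of their deviations of 0.0162, -0.0344 and 0.0288, so the numbers share no measurable pairing. The comparison by edgeR or DESeq2, planned for a table of counts, was not run. Depth limits linc-133, the piRNA genes and most tested genes of type ncRNA (780 of 1042 have a mean under 10 reads).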

Other observations

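The tests of protein families, gene types and other groupings of the libraries, the values without the authors' scaling, and the comparisons of parts of a list were chosen after the results had been seen. Protein families named in the table were tested as further groups, 229 in all, and 16 passed camera with its preset correlation (7 higher, 9 lower in the mutant), 0 of them with an estimated correlation (adjusted p = 0.978). Beside the chaperone families, the F-box associated family had a median log2 change of 0.42 over 98 genes, with 27 genes higher and 4 lower at an unadjusted p under 0.05. Genes with the F-box domain itself did not pass (median -0.16 over 93 genes, 4 higher and 13 lower at an unadjusted p under 0.05, camera adjusted p = 0.12), nor did the planned list of F-box and MATH-BATH genes (median 0.047 over 237 genes, adjusted p = 0.69), and differences between these sets were not tested. Genes with the Skp1 tetramerisation domain, which join F-box proteins to the ubiquitin ligase, had a median of 0.57 over 18 genes. Of 18 skr genes tested, 9 lay higher in every mutant library with an unadjusted p under 0.05, and 1, skr-5, lay lower by the same measure. skr-10 measured 17.99 ± 1.74 FPKM in wild type and 48.1 ± 13.8 FPKM in the mutant, and skr-7 measured 44.2 ± 5.46 and 90.6 ± 18.6 FPKM (SD, n = 3 each). Several of these genes are close copies of each other, so the level of a single one is uncertain. Genes with the FTH domain had a median of -0.16 over 117 genes and those with an ABC transporter domain a median of -0.18 over 46 genes.

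The mitochondrial chaperonin genes Y22D7AL.10 (Hsp10) and hsp-60 lie side by side and on opposite strands on chromosome III, from 1617145 to 1619004 and from 1619742 to 1625803. Both were higher in the mutant, 2.36-fold and 2.53-fold by means, while hsp-6, the mitochondrial Hsp70 gene, measured 182 ± 18.3 FPKM in wild type and 264 ± 149 FPKM in the mutant, with overlapping libraries. Among gene types, those of type ncRNA had a median log2 change of -0.33 over 1042 genes (camera adjusted p = 7.57e-06, and an adjusted p = 0.41 with an estimated correlation), of which 780 had a mean under 10 reads. snoRNA genes had a median of -0.32 over 95 genes (camera adjusted p = 0.00199) and miRNA genes -0.25 over 43 (camera adjusted p = 0.0299). Protein-coding genes had a median of 0.016 over 13868 (camera adjusted p = 0.00615). These 3 calls were lost with an estimated correlation (camera adjusted p of 0.393, 0.41 and 0.0921). Protein-coding genes held 98% to 98.7% of the reads of a library. Whether reads in short noncoding genes came from the mature RNAs or from longer transcripts over them was not tested. These medians therefore do not measure mature miRNA or snoRNA levels. The 13 tested genes of the mitochondrial chromosome held 0.00514% of the reads in wild-type replicate 1, where 8 of them had no read, against 0.0341% to 0.0682% in the other 5 libraries.

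The count of genes past the threshold, 0 in the real grouping, had 15 as its highest value among the other groupings of the 6 libraries, when wild-type replicate 1 was placed with mutant replicates 2 and 3. The number of genes with an unadjusted p under 0.05 was 2301, and the highest other was 1459. Of the lists, 3 passed, and the highest other was 19. Libraries that vary within a strain may account for such counts, since the preset correlation of 0.01 lies far below the estimated correlation of some lists (0.773 for insulin signalling), but the other groupings also hold part of the strain difference, and the parts were not tested separately. Chaperone members passing when adjusted over the list alone were 20, and the highest other was 0. In size the median log2 changes were 0.97 for the chaperones (highest other 0.61), 0.54 for the intracellular pathogen response (highest other 0.50) and 0.285 for the early embryo list (highest other 0.275). Groups of 3 against 3 allow only 10 groupings, too few for a share under 0.05.

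The higher chaperone levels in the mutant were weighed against technical causes. The authors' scaling shifts all genes of a library alike and hardly differs between the strains: without it the median of all genes was -0.0132, against -0.00147 with it, and the list median was 0.96, against 0.97. The size of these factors, rather than any test of the genes, leaves them too small to give the pattern, and another normalization fault was not tested by it. Without 1 mutant library the median was still at least 0.695, the value without mutant replicate 3, which argues against a single library as the whole cause. The rise was uneven between libraries. Relative to each gene's mean log2 value, the median member lay at 0.167, 0.338 and 1.04 in mutant replicates 1, 2 and 3. In wild-type replicates 1, 2 and 3 it lay at -0.458, -0.434 and -0.445. The 25 members outside the hsp-16 genes had a median of 0.72, with 18 of them separated completely. That argues against reads shared among the hsp-16 copies. A stress at collection that only the mutant cultures met could give the same pattern: the heat-inducible members changed by 2.11 more on the log2 scale than the others (medians 2.72 and 0.61), and hsp-16.2 was 4.55 times as high in wild-type replicate 1 as in the mean of the other wild-type libraries. Such a stress and an effect of the allele cannot be told apart, since the labels give no collection batches, and the allele stays an untested explanation.

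The lower intracellular pathogen response was weighed in the same way. Without each wild-type library in turn the median stayed at -0.396 or below, which argues against a single wild-type library as the cause. Wild-type replicate 1 lay at the level of mutant replicates 1 and 3, and without it the median was -0.65. The difference thus rests mainly on wild-type replicates 2 and 3. The 10 members outside the pals family had a median of -0.54, the same as the whole list. Of these 10, 3 lay lower in every mutant library, against 15 of all 40 members. The change was thus not confined to the pals genes. With few members separated completely, reads shared among the copies stay open for the pals genes themselves. An effect of the allele was not tested apart from these.

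The early embryo list may reflect embryos carried over with the mutant larvae, since eggs were placed in buffer. Maternally loaded members had a median log2 change of 0.074, against 0.43 for the 34 members transcribed in the embryo, a difference that was not tested. The level of the maternally loaded members in wild type was higher, with a median of 18.1 FPKM against 2.47 FPKM, and could hide a small share, so carry-over and an effect of the allele cannot be told apart. Genes near the detection limit stay open as well: among members with a mean of at least 5 FPKM, 24 in all, the median was 0.13, against 0.28 over all 48, and the call was lost, with fewer genes tested.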
